A study of Mus musculus with 24 samples.

How the data were processed

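Bulk RNA-seq read counts per gene were analysed from alveolar macrophages sorted from mice that carried an Ms4a3-driven tdTomato fate reporter. Each of the 24 libraries was made from 100000 sorted cells of a pool of 2 mice, about 16 h after the last exposure, in 6 groups of 4 libraries. The groups were room air, tdTomato-negative smoke and tdTomato-positive smoke, each at 4 and at 12 weeks. The counts were made by the authors, whose processing notes name STAR for alignment to GRCm38, featureCounts of Subread 2.0.2 for counting and DESeq2 for testing. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Values in the table were whole numbers and were taken as raw counts. A further 12 columns of that table belong to samples not analysed here.

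The table held 56726 Ensembl gene identifiers. A symbol was found for 51880 of them in GENCODE vM21 (GRCm38), and 4846 had none and held a median of 0.432% of counts per library, at most 0.782% in a full-depth library. Since 65 symbols belonged to several identifiers, tests used identifiers. Reads of close paralogs and of overlapping genes may be shared between them, which touches Ear1 and Ear2, Ifit3 and Ifit3b, Hspa1a and Hspa1b, the H2 genes, Ly6c2, and Mmp12 with Mmp1b.

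Library totals ran from 17.0 M to 45.02 M counts in 23 libraries, median 24.8 M at 4 weeks and 36.6 M at 12 weeks. The remaining library, tdTomato-positive replicate 2 at 12 weeks, had 12656 counts. It was kept because the design fixed before the files were opened held all 24 libraries, and its TMM factor was 1.90. Without it 14 gene list calls by camera were lost and 41 gained of 330, and only some of these are given. An upper limit for a count of 0 was set at 3 counts, which is 0.0666 to 0.177 CPM in full-depth libraries and 237 CPM in the shallow one before TMM scaling, counting error only. The share of mitochondrial counts was 3.62 ± 0.68, 3.36 ± 1.27 and 2.25 ± 0.61% (SD, n = 4) in room air, tdTomato-negative and tdTomato-positive cells at 4 weeks. At 12 weeks it was 4.59 ± 0.91 and 5.44 ± 0.91% (SD, n = 4) and 3.72 ± 0.83% (SD, n = 3).

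Genes were kept with filterByExpr of edgeR at a minimum count of 10, which left 22101 genes, or 22961 without the shallow library. A model of the 6 groups with TMM factors was fitted with the robust quasi-likelihood method of edgeR (18 residual degrees of freedom). Smoke was compared with room air and tdTomato-positive with tdTomato-negative cells within each time, room air at 12 with 4 weeks, and the smoke effects and the lineage difference at 12 with those at 4 weeks. P values were adjusted by Benjamini-Hochberg within each comparison and called at 0.05, with no minimum fold change. The SE of a log2 fold change was its size divided by the square root of F. Tests ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and figures in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

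Gene groups were 35 lists written before the data were examined. They cover resident, monocyte-derived, interstitial and lipid-associated macrophages, MHC class I and II, cytokines, interferon, targets of AhR and NRF2, matrix proteases, lipid uptake and efflux, cholesterol synthesis, fatty acid oxidation, lysosome, proliferation, glycolysis, respiratory chain, iron, growth factors and efferocytosis. Markers of other cells were neutrophil, eosinophil, dendritic, T and NK, B, epithelial, endothelial and mesenchymal, and mast, basophil and erythroid cells. Technical lists were dissociation stress, ribosomal proteins, mitochondrial RNA, the circadian clock, sex-linked genes, and sort and lineage genes. Of these, 33 were tested with camera on log2 CPM (prior count 2) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment, and again with an estimated correlation and with fry. The eosinophil list, with 2 genes tested, and the sex-linked list, with 1, are given as counts. A count "adjusted over the list alone" used Benjamini-Hochberg within the list.

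Genes were named by rule: the 6 largest rises and falls within each comparison among genes called, with a mean log2 CPM of at least 3, no overlap between the groups and a named product, the 4 largest for comparisons between times, up to 4 members of smallest p per list, and 12 genes fixed in advance. The fixed genes reported were Ms4a3, Siglecf, Itgax, Ccr2, Mmp12, Spp1, Il1b, Cyp1b1, Nqo1, Gpnmb and Car4, and some genes covered by these rules are not reported here. The overlap condition used all libraries of a group, the shallow one included, where 1 count is 79.0 CPM before scaling. With a count of 0 there, a gene could be named as lower in tdTomato-positive cells at 12 weeks, but not as higher. Against room air 1751 genes met the conditions in those cells, and 3319 to 4143 in the other smoke groups. Between lineages at 12 weeks 16 met them, and no rise was named by rank. Genes chosen after their values were seen are marked so.

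Pairing was checked on 9065 genes in full-depth libraries by correlating deviations from the group mean. Same-number tdTomato-negative and tdTomato-positive libraries gave 0.334 to 0.828 at 4 weeks and 0.300 to 0.677 at 12 weeks, against -0.72 to 0.47 and -0.42 to 0.61 for other numbers, and room air and smoke libraries of the same number gave -0.13 to 0.38. These ranges overlap: at 12 weeks tdTomato-positive replicate 4 gave 0.61 with tdTomato-negative replicate 2 and 0.300 with its own number. Libraries of the same number were taken as pairs from 1 pool, which the correlations alone do not settle. Pool as a block had been set in advance as an alternative. The same steps were also run on data simulated from the room air and tdTomato-negative libraries of 4 weeks alone, with 200 changed genes of 19129. That run lacked the 6 groups and the shallow library of the main fit. It also had fewer changed genes than any smoke comparison with room air called, so its figures do not describe the main fit. It recovered 73 of 100 genes at an absolute log2 fold change of 1 and 99 of 100 at 2, and called 12 unchanged genes.

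Alternatives set before the files were opened were DESeq2, RLE factors, no count filter, a stricter filter (mean CPM of at least 5), voom with quality weights, a separate fit per time, pool as a block, an absolute log2 fold change of at least 1, and leaving out each library. For lists they were an estimated correlation, fry and a block in camera, and for overlaps DESeq2 calls and room air libraries split between the lineages. Runs without the shallow library in camera, in the block fit and with RLE factors were added after it had been seen.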

Results

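The measurements were bulk RNA-seq read counts per gene from mouse alveolar macrophages, the phagocytes of the lung's air spaces, sorted by flow cytometry as live CD45+ CD11c+ SiglecF+ cells from digested lungs. The mice carried a tdTomato fate reporter driven by Ms4a3, a gene of granulocyte and monocyte progenitors, so a tdTomato-positive macrophage descends from such a progenitor and a tdTomato-negative macrophage lacks that mark. Mice breathed room air or were exposed to cigarette smoke for 4 or 12 weeks. Macrophages of smoke-exposed mice were sorted into tdTomato-negative and tdTomato-positive cells, and those of room air mice were not split. This gave 6 groups of 4 libraries, 24 in all, and each library held cells pooled from 2 mice, 8 mice per group. Libraries of the same number within a time, tdTomato-negative and tdTomato-positive, were taken to come from the same pool of smoke-exposed mice.

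Total counts per library, in units of M (mega), were 44.7, 25.4, 21.1 and 28.8 in room air at 4 weeks. They were 22.0, 23.6, 24.9 and 21.4 in tdTomato-negative smoke cells, and 24.7, 27.4, 26.001 and 21.5 in tdTomato-positive smoke cells at 4 weeks. At 12 weeks they were 17.0, 30.5, 35.1 and 38.1 in room air and 28.9, 39.2, 36.6 and 39.1 in tdTomato-negative smoke cells. In tdTomato-positive smoke cells at 12 weeks they were 35.9, 0.013, 45.02 and 43.5. Replicate 2 of that last group thus held 12656 counts over 2419 genes, where 1 count equalled 79.0 CPM (counts per M counts of a library, before scaling). It limits every comparison that uses tdTomato-positive cells at 12 weeks, also those between the times. Through the shared fit it also moved other comparisons. For tdTomato-negative cells against room air at 4 weeks, 4107 genes were called higher and 3404 lower with it, and 4524 and 3148 without. Levels are given as CPM scaled by TMM factors, as mean ± SD, and those of that group are over its 3 full-depth libraries. In a full-depth library a count of 0 allows a level of up to 0.0666 to 0.177 CPM before scaling, counting error only. Ms4a3 itself was at most 0.347 CPM in any full-depth library and was not tested.

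The question at 4 weeks was how smoke altered alveolar macrophages without the lineage mark and those with it. In tdTomato-negative cells, Mmp12 (ENSMUSG00000049723, GRCm38 chromosome 9, 7344381 to 7369499), which encodes macrophage elastase, stood at 2185 ± 155 CPM (SD, n = 4) against 9.12 ± 2.08 CPM (SD, n = 4) in room air. That was a rise of 7.91 ± 0.39 log2 units (SE), the largest among the 3319 genes that passed every condition for naming. Its annotated interval overlaps Mmp1b on the other strand, and the strand setting of the counting is not given in the sources used here. Next came C1qc, a subunit of the complement component C1q, at 101 ± 23.4 CPM (SD, n = 4) against 0.690 ± 0.406 CPM, and Ccl2, a chemokine that recruits monocytes, at 100.1 ± 22.6 CPM against 0.828 ± 0.186 CPM. Itgam, the integrin CD11b of monocytes, rose by 6.55 ± 0.37 log2 units. The largest falls among those 3319 genes were in Cpne5, a calcium-dependent membrane-binding protein, from 233 ± 17.1 to 11.1 ± 1.52 CPM, and in the adhesion gene Epcam, from 57.0 ± 10.9 to 3.10 ± 1.83 CPM. Ear1 (ENSMUSG00000072601), a ribonuclease of resident alveolar macrophages with close paralogs, fell from 684 ± 76.5 to 58.2 ± 19.0 CPM.

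Gene lists written down in advance gave the wider picture in these tdTomato-negative cells. Of 24 monocyte-derived macrophage genes, 18 were higher and 6 did not pass (20 higher adjusted over the list alone), with Ms4a7 3.01 log2 units up. Of 24 resident alveolar macrophage genes, 15 were lower and 5 higher (16 and 5 adjusted over the list alone), among them Flt1, down by 2.39, and Cidec, a lipid droplet gene, down by 3.51. Higher genes numbered 20 of 24 for matrix proteases, 25 of 33 for inflammatory cytokines, 25 of 30 for the interferon response, 12 of 13 for interstitial macrophages, 14 of 20 for lipid-associated macrophages and 24 of 36 for the lysosome. Adjusted over the list alone these were 21, 26, 26, 13, 14 and 25. Examples were the protease Plau (2.88), the chemokine Ccl9 (4.15), the interferon-induced Oas1a (2.26), the lipid receptor Trem2 (2.28) and the tetraspanin Cd63 (3.19). For MHC class II, whose products present peptides to T cells, 9 of 13 were higher and H2-DMa was lower by 1.36, and H2-Eb1 stood at 385 ± 181 CPM (SD, n = 4) against 70.0 ± 4.58 CPM (9 higher and 2 lower adjusted over the list alone). Of 24 cholesterol synthesis genes 15 were lower, such as Cyp51 by 1.11, and 1 was higher, counts that stayed the same adjusted over the list alone. Proliferation genes were higher in 12 of 30 (16 adjusted over the list alone), among them Rrm2 at 1.26.

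Marker lists of other cell types moved in these libraries too. Dendritic cell genes were higher in 8 of 11, T and NK cell genes in 6 of 16, epithelial genes in 11 of 13 and endothelial and mesenchymal genes in 10 of 13. Sftpc, a surfactant gene of alveolar epithelium, was at 240 ± 174 CPM (SD, n = 4) in tdTomato-negative smoke cells and at 51.0 ± 16.5 CPM in room air, and Ccr7, carried by migrating dendritic cells, at 17.4 ± 14.7 against 1.14 ± 0.244 CPM.

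The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 22101 genes called 4107 genes higher and 3404 lower in tdTomato-negative smoke cells at 4 weeks. With RLE factors, which move the median of all genes by -0.12 log2 units, the counts were 3357 and 4387, and with RLE factors and without the shallow library 4109 and 3556. Adjusted p was 4.5e-14 for Mmp12, 4.9e-19 for Cpne5 and 1.1e-12 for Ear1. By camera with its preset correlation, adjusted p was 2.1e-12 for the monocyte-derived list, 6.6e-23 for matrix proteases, 2.0e-18 for cytokines, 1.8e-15 for interferon, 2.3e-16 for interstitial, 4.3e-14 for lipid-associated, 7.4e-10 for lysosome, 2.1e-04 for resident and 0.0263 for MHC class II genes. With an estimated correlation none of the 19 calls held, with an adjusted p of 0.0509 for interstitial, 0.0620 for protease, 0.260 for monocyte-derived and 0.581 for resident genes. The camera test did not call cholesterol synthesis (adjusted p = 0.197) or proliferation (adjusted p = 0.178), and without the shallow library it called both (9.5e-04 and 0.00734).

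In tdTomato-positive cells at 4 weeks the largest rise among genes that met the conditions for naming was again in Mmp12, to 2946 ± 338 CPM (SD, n = 4), 325 times the room air level. Inhba, an activin subunit, stood at 178 ± 27.9 CPM against 0.617 ± 0.421 CPM, and Il7r, a cytokine receptor, at 404 ± 62.8 CPM against 1.86 ± 0.498 CPM. Cpne5 fell to 2.09 ± 0.226 CPM, Cidec from 281 ± 23.9 to 4.65 ± 1.34 CPM and Ear1 to 14.1 ± 3.61 CPM (SD, n = 4). Siglecf (ENSMUSG00000039013, chromosome 7, 43351341 to 43359531), the gene of a receptor used in the sort, was at 368 ± 17.0 CPM in room air, 64.5 ± 20.4 CPM in tdTomato-negative and 19.3 ± 6.23 CPM in tdTomato-positive cells (SD, n = 4 each). Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), the receptor for Ccl2, was at 11.5 ± 0.523, 30.9 ± 8.37 and 60.6 ± 11.3 CPM in the same order.

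Of the monocyte-derived list 23 of 24 genes were higher in tdTomato-positive cells (24 adjusted over the list alone), including Cx3cr1 at 3.10 log2 units. Of the resident list 19 of 24 were lower and 3 higher, the same adjusted over the list alone, with Fabp1 down by 7.38. Higher genes numbered 22 of 24 for proteases, 28 of 33 for cytokines, 27 of 30 for interferon, 10 of 13 for MHC class II, 15 of 20 for lipid-associated, 26 of 36 for lysosome and 14 of 21 for glycolysis genes. Adjusted over the list alone these were 22, 28, 28, 10, 15, 27 and 16. Examples were the collagenase gene Mmp8 (3.13), H2-Ab1 (2.76; ENSMUSG00000073421), Gpnmb (3.61), a lysosomal glycoprotein gene, and the glucose transporter Slc2a1 (2.61). Of 22 fatty acid oxidation genes 13 were lower (15 adjusted over the list alone), such as Acaa1a by 1.27 and Hadha by 1.06. Mitochondrially encoded genes were lower in 8 of 13 (8 adjusted over the list alone), mt-Nd2 by 1.36, and the share of mitochondrial counts was 2.25 ± 0.61% against 3.62 ± 0.68% in room air (SD, n = 4). Dendritic cell genes were higher in 9 of 11, with Cd24a at 2.01, neutrophil genes in 4 of 11, with S100a8 at 2.23, epithelial genes in 6 of 13, with Hopx at 3.02, and endothelial and mesenchymal genes in 9 of 13.

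In this comparison 4691 genes were called higher and 4662 lower by edgeR, against 3629 and 6031 with RLE factors (median shift -0.16) and 4861 and 4647 with RLE factors and without the shallow library. The adjusted p (Benjamini-Hochberg) was 1.1e-14 for Mmp12, 4.2e-12 for Siglecf and 2.5e-12 for Ccr2. The camera adjusted p was 1.1e-17 for monocyte-derived, 7.0e-11 for resident, 4.4e-24 for protease, 2.0e-18 for cytokine, 5.1e-16 for interferon, 5.4e-04 for MHC class II, 5.1e-14 for lipid-associated, 4.9e-12 for lysosome and 2.2e-05 for glycolysis genes. None of the 17 lists called held with an estimated correlation (adjusted p = 0.145 for monocyte-derived, 0.312 for resident and 0.0943 for protease genes). Camera did not call fatty acid oxidation (0.0821) or mitochondrial genes (0.0562), and did so without the shallow library (4.9e-04 and 0.0441).

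**Figure D1:**
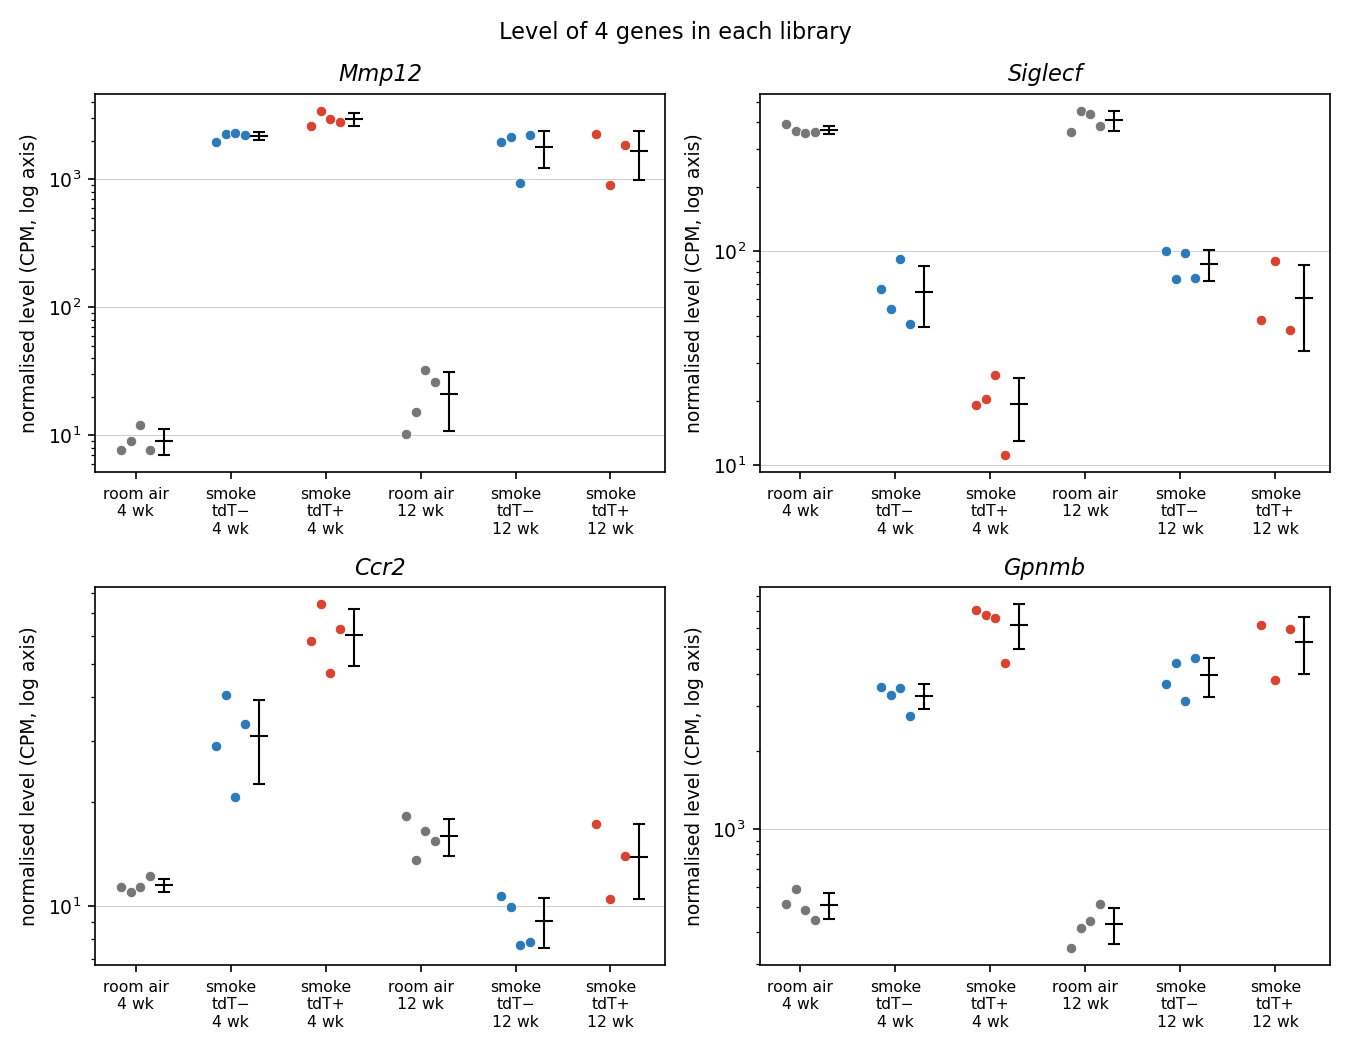
Level of Mmp12, Siglecf, Ccr2 and Gpnmb in each full-depth library (log axis, CPM), by group: room air in grey, tdTomato-negative smoke in blue, tdTomato-positive smoke in red, with black dashes and bars for mean ± SD. Siglecf at 4 weeks was at 368 CPM in room air, 64.5 CPM in tdTomato-negative and 19.3 CPM in tdTomato-positive cells, and Ccr2 at 12 weeks was at 15.9, 9.04 and 13.9 CPM.

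The next question was how the lineages differed from each other within the smoke-exposed mice. At 4 weeks, tdTomato-positive cells had less of the resident program: 18 of 24 genes were lower (19 lower and 1 higher adjusted over the list alone), with Ear1 down by 2.04 ± 0.22, Cidec by 2.41 ± 0.26 and the keratin Krt19 by 2.34 ± 0.26 log2 units. Marco, a scavenger receptor, was at 53.2 ± 18.3 CPM against 241 ± 44.9 CPM (SD, n = 4). Siglecf was lower by 1.74 ± 0.24, and Htr2c, a serotonin receptor gene, at 12.7 ± 4.115 against 77.5 ± 19.3 CPM, was the largest fall among genes that met those conditions. Car4, a carbonic anhydrase gene of resident cells, was lower by 1.10 ± 0.22, as it rose with smoke in tdTomato-negative cells, to 706 ± 204 CPM (edgeR adjusted p = 3.1e-04), while in tdTomato-positive cells it stood at 329 ± 111 CPM against 327 ± 66.2 CPM in room air (SD, n = 4 each). Higher genes included Hpse, a heparanase gene, at 89.5 ± 30.1 against 21.9 ± 7.37 CPM, the proteoglycan Vcan (1.82 ± 0.36), Csf3r (1.70 ± 0.17), the receptor of the granulocyte growth factor, and Ccr2 (0.97 ± 0.17). Of the monocyte-derived list 7 of 24 were higher (12 adjusted over the list alone), Ccr1 among them at 0.52. Gpnmb (ENSMUSG00000029816) was higher by 0.92 ± 0.19, while Mmp12 (0.43 ± 0.29) did not pass. With pool as a block in edgeR, which treats libraries of the same number as pairs, Mmp12 passed (0.44, adjusted p = 0.0405).

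Of 24 protease genes 4 were higher and 1 lower (10 and 2 adjusted over the list alone), with Mmp8 up by 0.79. Glycolysis genes were higher in 4 of 21 (5 adjusted over the list alone), such as Pfkl at 0.46, and proliferation genes were lower in 4 of 30 (15 adjusted over the list alone), such as Bub1b by 0.72. Neutrophil genes were higher in 4 of 11 and lower in 1, the same adjusted over the list alone, and those higher include Csf3r and Mmp8, which room air macrophages also carried at 30.8 ± 2.93 and 48.3 ± 5.93 CPM (SD, n = 4). Those higher also include S100a9, a calcium-binding protein gene of neutrophils, at 3.06 ± 0.747 against 0.128 ± 0.115 CPM (SD, n = 4), and Retnlg, at 1.24 ± 0.493 against 0.0657 ± 0.0855 CPM, a call lost without any of the 8 libraries compared (edgeR adjusted p from 0.0504 to 0.104). The CD11c+ SiglecF+ gate of the sort is meant to leave neutrophils out, but the purity of the sorted cells is not in these data, so a small share of neutrophil RNA in tdTomato-positive libraries is not excluded. For MHC class II, 4 of 13 were higher (8 adjusted over the list alone), led by Cd86 at 0.74 ± 0.19, a call lost without tdTomato-negative replicate 1 (edgeR adjusted p = 0.0649) or 3 (0.0683) or tdTomato-positive replicate 2 (0.0878). Epithelial genes were higher in 1 of 13, dendritic cell and endothelial genes in 0 of 11 and 0 of 13.

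The test called 356 genes higher and 750 lower in tdTomato-positive than in tdTomato-negative cells at 4 weeks (edgeR quasi-likelihood, Benjamini-Hochberg), with an adjusted p of 1.4e-06 for Ear1, 9.6e-08 for Htr2c, 8.2e-05 for Siglecf, 7.3e-04 for Hpse and 4.3e-04 for Ccr2. With pool as a block the counts were 1249 and 1321. Without a library, the higher count was 193 (tdTomato-negative replicate 1), 237 (tdTomato-negative replicate 3), 217 (tdTomato-positive replicate 1) or 176 (tdTomato-positive replicate 2), and the lower count 487, 478 and 467 without the first 3 of these. The camera adjusted p was 4.6e-21 for resident, 5.6e-10 for monocyte-derived, 5.3e-08 for protease, 2.9e-04 for glycolysis, 1.5e-05 for neutrophil, 6.8e-05 for MHC class II and 0.0445 for proliferation genes. The adjusted p with an estimated correlation was 0.222, 0.479, 0.479, 0.845, 0.187, 0.479 and 0.998, so none of the 15 calls held.

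At 12 weeks the same questions were asked in other mice. In tdTomato-negative cells Mmp12 was at 1804 ± 588 CPM against 21.0 ± 10.2 CPM in room air (SD, n = 4), and the complement receptor C3ar1 at 179 ± 46.3 against 2.46 ± 1.09 CPM. Syngr1, a vesicle protein gene, rose by 6.34 ± 0.33 and C1qc by 5.94 ± 0.43 log2 units. Epcam fell from 95.4 ± 17.4 to 1.68 ± 0.153 CPM, Cpne5 from 232 ± 25.3 to 11.6 ± 2.75 CPM and Hr, a nuclear corepressor gene, from 219 ± 12.3 to 12.4 ± 2.38 CPM. Ccr2 was lower, at 9.04 ± 1.495 against 15.9 ± 1.93 CPM (-0.81 ± 0.17). Spp1 (ENSMUSG00000029304), which encodes osteopontin, was at 6604 ± 2487 against 292 ± 51.4 CPM, and Gpnmb at 3938 ± 681 against 428 ± 68.5 CPM.

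MHC class II genes, higher with smoke at 4 weeks, were lower in 10 of 13 and higher in 2 in tdTomato-negative cells at 12 weeks, the same adjusted over the list alone. Cd74, the invariant chain, was at 530 ± 101 against 2326 ± 329 CPM (SD, n = 4), and Ciita, the transactivator of the class, fell by 2.31. Lysosome genes were higher in 31 of 36 (31 adjusted over the list alone), with Gla at 1.44. Higher genes numbered 15 of 20 for lipid-associated, 17 of 24 for protease, 17 of 30 for interferon, 13 of 13 for interstitial, 12 of 24 for monocyte-derived, 21 of 29 for respiratory chain and 17 of 30 for ribosomal protein genes. Adjusted over the list alone these were 16, 18, 18, 13, 13, 23 and 24. Examples were Trem2 (2.74), the cathepsin Ctsl (2.02), Oas1a (1.92), Ms4a7 (3.54), Sdhb (0.79) and Rps2 (0.80). Cytokine genes went both ways, 16 higher and 7 lower of 33 (16 and 7 adjusted over the list alone), with Ccl2 at 83.6 ± 25.9 against 6.50 ± 1.58 CPM. Of the resident list 10 of 24 were lower and 6 higher (12 and 6 adjusted over the list alone), with Ear1 down by 2.67 and Flt1 by 2.69. Dissociation stress genes were lower in 10 of 20 and higher in 2 (12 and 2 adjusted over the list alone), such as Atf3 by 1.59. Endothelial and mesenchymal genes were higher in 7 of 13, dendritic cell genes in 5 of 11 with 2 lower, epithelial genes in 5 of 13 with 1 lower, and Sftpc was at 82.2 ± 3.28 against 71.5 ± 30.9 CPM.

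Over all genes edgeR called 4231 higher and 4029 lower in tdTomato-negative cells at 12 weeks, against 2675 and 5879 with RLE factors (median shift -0.21), and 3898 and 4443 with RLE factors and without the shallow library. The adjusted p (Benjamini-Hochberg) was 7.1e-13 for Mmp12, 2.7e-07 for Cd74 and 4.7e-04 for Ccr2. The camera adjusted p was 0.00181 for MHC class II, 2.9e-21 for lysosome, 2.5e-18 for lipid-associated, 2.5e-18 for protease, 1.9e-05 for interferon, 6.4e-16 for interstitial, 1.9e-05 for monocyte-derived, 4.2e-06 for cytokine, 0.0117 for respiratory chain, 3.3e-05 for ribosomal and 0.00215 for stress genes. With an estimated correlation none of the 19 calls held (adjusted p = 0.652 for MHC class II, 0.2496 for lysosome and 0.0590 for interstitial genes). The resident list had a camera adjusted p of 0.128, and 0.0439 without the shallow library.

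In tdTomato-positive cells at 12 weeks, Mmp12 was at 1675 ± 693 CPM (SD, n = 3), Syngr1 at 139 ± 27.2 against 1.13 ± 0.804 CPM, Slamf7, a receptor of activated leukocytes, at 160.5 ± 63.5 against 2.22 ± 0.985 CPM, and Fstl1, a secreted glycoprotein gene, at 576.5 ± 59.6 against 8.29 ± 0.758 CPM. Cpne5 was at 8.17 ± 1.49 CPM, Cidec at 12.0 ± 3.10 against 281.5 ± 33.7 CPM, and Krt79, a keratin gene of resident cells, at 40.6 ± 10.3 against 570.4 ± 44.1 CPM. Siglecf was at 60.3 ± 26.01 against 408 ± 42.4 CPM, Car4 was higher by 1.55 ± 0.24 log2 units, and Ccr2, at 13.9 ± 3.396 against 15.9 ± 1.93 CPM, did not pass (-0.20 ± 0.18, edgeR adjusted p = 0.401).

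Lysosome genes were higher in 31 of 36 (31 adjusted over the list alone), with Gla at 1.73, and all 30 ribosomal protein genes were higher (30 adjusted over the list alone), with Rps19 at 1.10. From 4 to 12 weeks the ribosomal list fell in room air, by a median of -0.60 log2 units over full-depth libraries. In smoke cells its median change was -0.23 (tdTomato-negative) and -0.11 (tdTomato-positive). Higher genes numbered 16 of 20 for lipid-associated, 19 of 24 for protease, 17 of 30 for interferon, 17 of 24 for monocyte-derived, 11 of 13 for interstitial and 24 of 29 for respiratory chain genes. Adjusted over the list alone these were 16, 19, 19, 17, 11 and 24. Examples were Gpnmb (3.56), Ctsl (2.26), Usp18 (3.92), C1qa (5.21) and Cyc1 (0.88). MHC class II genes were lower in 10 of 13 and higher in 2 (the same adjusted over the list alone), with Cd74 at 533 ± 170 CPM (SD, n = 3). Of the resident list 12 of 24 were lower and 5 higher (13 and 5 adjusted over the list alone), with Flt1 down by 3.57. Of the cytokines 16 of 33 were higher and 8 lower (17 and 8 adjusted over the list alone). Dendritic cell genes were higher in 1 of 11 and lower in 2, epithelial genes higher in 3 of 13 and lower in 2, and endothelial genes higher in 4 of 13.

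The edgeR quasi-likelihood test called 4887 genes higher and 5179 lower in tdTomato-positive cells at 12 weeks, against 2810 and 7478 with RLE factors (median shift -0.29). With RLE factors and without the shallow library they were 4653 and 5501. The adjusted p (Benjamini-Hochberg) was 1.1e-12 for Mmp12, 2.1e-08 for Siglecf and 5.0e-07 for Cd74. The camera adjusted p was 4.4e-29 for lysosome, 7.2e-12 for ribosomal, 7.3e-24 for lipid-associated, 4.0e-21 for protease, 9.2e-05 for interferon, 1.4e-06 for monocyte-derived, 5.0e-09 for interstitial, 0.00624 for respiratory chain and 4.4e-06 for cytokine genes. None of the 16 calls held with an estimated correlation (adjusted p = 0.121 for lysosome, 0.548 for ribosomal and 0.819 for respiratory chain genes). Fry gave the opposite direction for the interferon and respiratory chain lists and called neither. MHC class II (0.0582) and resident genes (0.263) were not called by camera, and were without the shallow library (0.00199 and 0.0229).

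**Figure D2:**
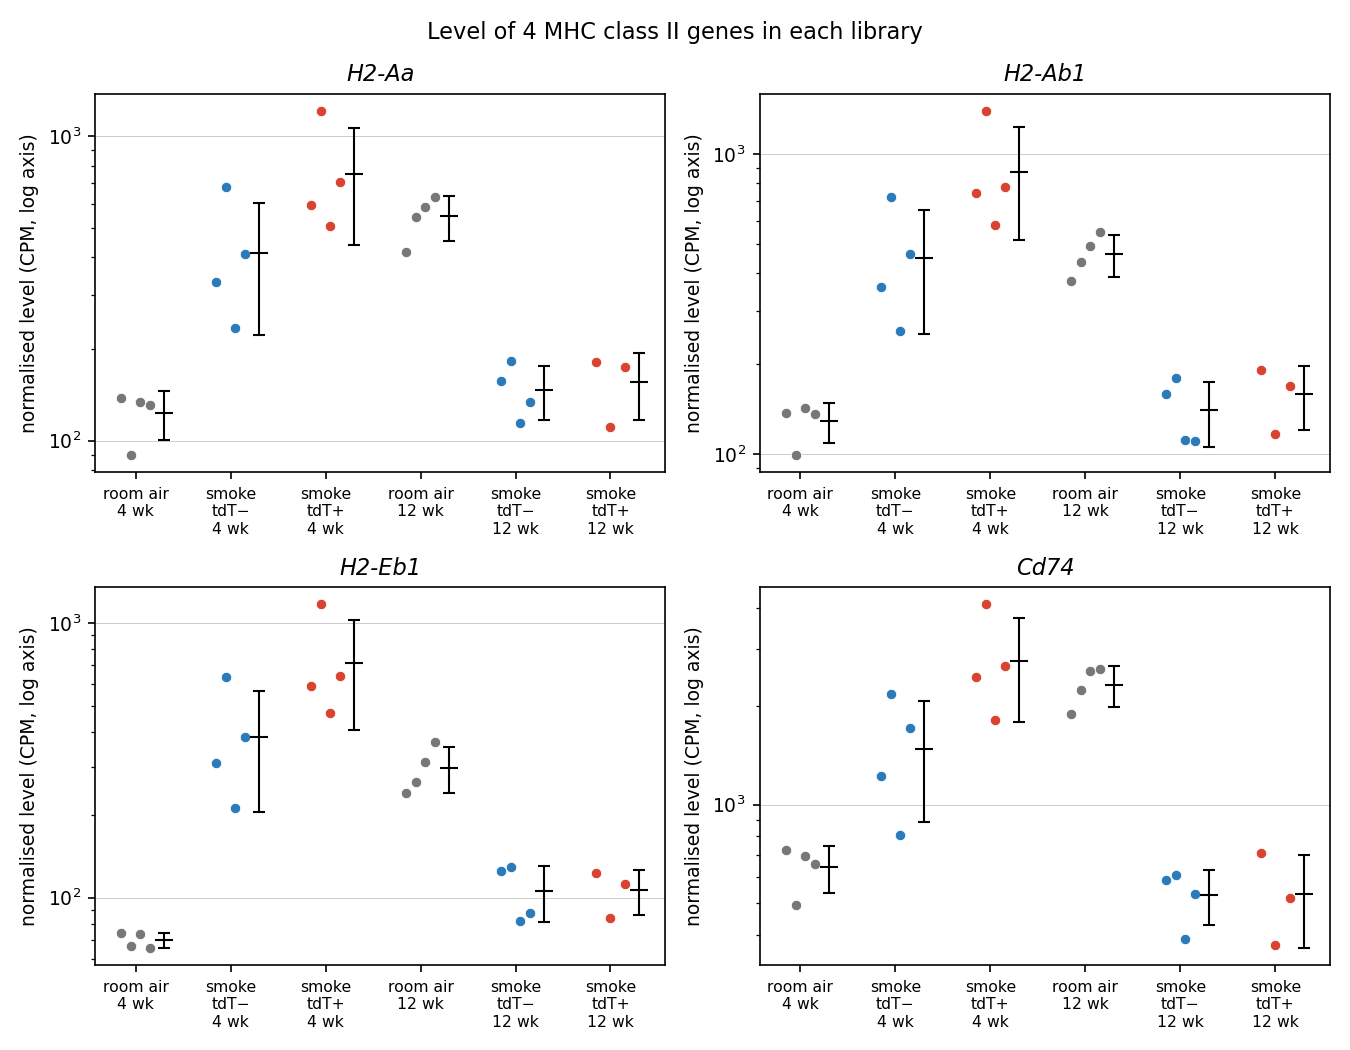
Level of the MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 in each full-depth library (log axis, CPM), in the colours of the plot of Mmp12 and Siglecf, with mean ± SD in black. Cd74 stood at 643 CPM in room air and 1482 and 2758 CPM in smoke at 4 weeks, and at 2326, 530 and 533 CPM at 12 weeks.

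Between the lineages at 12 weeks, the number of genes called depended on the fit, 19 higher and 79 lower without the shared pools in the model and 315 and 583 with pool as a block. Gt(ROSA)26Sor, a noncoding RNA of the locus that commonly carries such reporters, was higher by 1.39 ± 0.13 log2 units in tdTomato-positive cells, and was singled out after its values were seen. Kitl, the ligand of the receptor Kit, was at 15.8 ± 1.66 CPM (SD, n = 3) against 38.1 ± 7.77 CPM (SD, n = 4). Ddah1, an enzyme of arginine metabolism, was at 6.13 ± 2.82 against 48.6 ± 23.4 CPM, a call lost without tdTomato-positive replicate 1 (edgeR adjusted p = 0.0694). Of the resident list Flt1, Cidec and Marco were lower among 24 (4 lower adjusted over the list alone), Flt1 by 0.87 ± 0.19. Each of these 3 calls was lost without tdTomato-negative replicate 1 or 2 or tdTomato-positive replicate 1 or 4, with an edgeR adjusted p for Cidec of 0.0801, 0.0644, 0.0534 and 0.165. Siglecf (-0.53 ± 0.25) and Ccr2 (0.61 ± 0.18) did not pass. With pool as a block in edgeR they did, Siglecf at -0.67 (adjusted p = 0.00794) and Ccr2 at 0.64 (adjusted p = 0.00286), and so they did without tdTomato-positive replicate 3 (adjusted p = 0.0479 and 0.0170). Without the block no monocyte-derived, MHC class II, lysosome or ribosomal gene was called, while the block in edgeR called some, such as Ccr2 and the MHC class II gene Ciita (-0.59, adjusted p = 0.0415). Among interstitial macrophage genes Gas6, a bridging molecule for dying cells, was lower by 1.74 ± 0.36, 1 of 13 (8 lower adjusted over the list alone), a call lost without tdTomato-negative replicate 2 or 4 or tdTomato-positive replicate 1 or 4 (edgeR adjusted p = 0.0955, 0.0942, 0.219 and 0.130).

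The edgeR quasi-likelihood test called 19 genes higher and 79 lower between the lineages at 12 weeks, with an adjusted p of 3.1e-07 for Gt(ROSA)26Sor, 1.6e-04 for Kitl and 0.00463 for Ddah1 (Benjamini-Hochberg). The counts without the block rested on single libraries: without tdTomato-positive replicate 1 they were 1 and 18, without replicate 3 153 and 322, without replicate 4 4 and 24, and without the shallow replicate 2 12 and 65. Without tdTomato-negative replicate 1, 2, 3 or 4 the higher count was 6, 6, 9 or 6, and the lower 35, 34 and 41 without replicate 1, 2 or 4. Camera called lysosome (adjusted p = 3.3e-06), ribosomal (2.9e-08) and interstitial genes (0.0415), median log2 difference 0.12, 0.30 and -0.76, and none of the 11 calls held with an estimated correlation (adjusted p = 0.968 for each of these). Camera gave the shallow library the same weight as the others. Fry gave the opposite direction for the lysosome and ribosomal lists and called neither. The resident list (0.596) was called without the shallow library (0.0216), median -0.18.

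**Figure D3:**
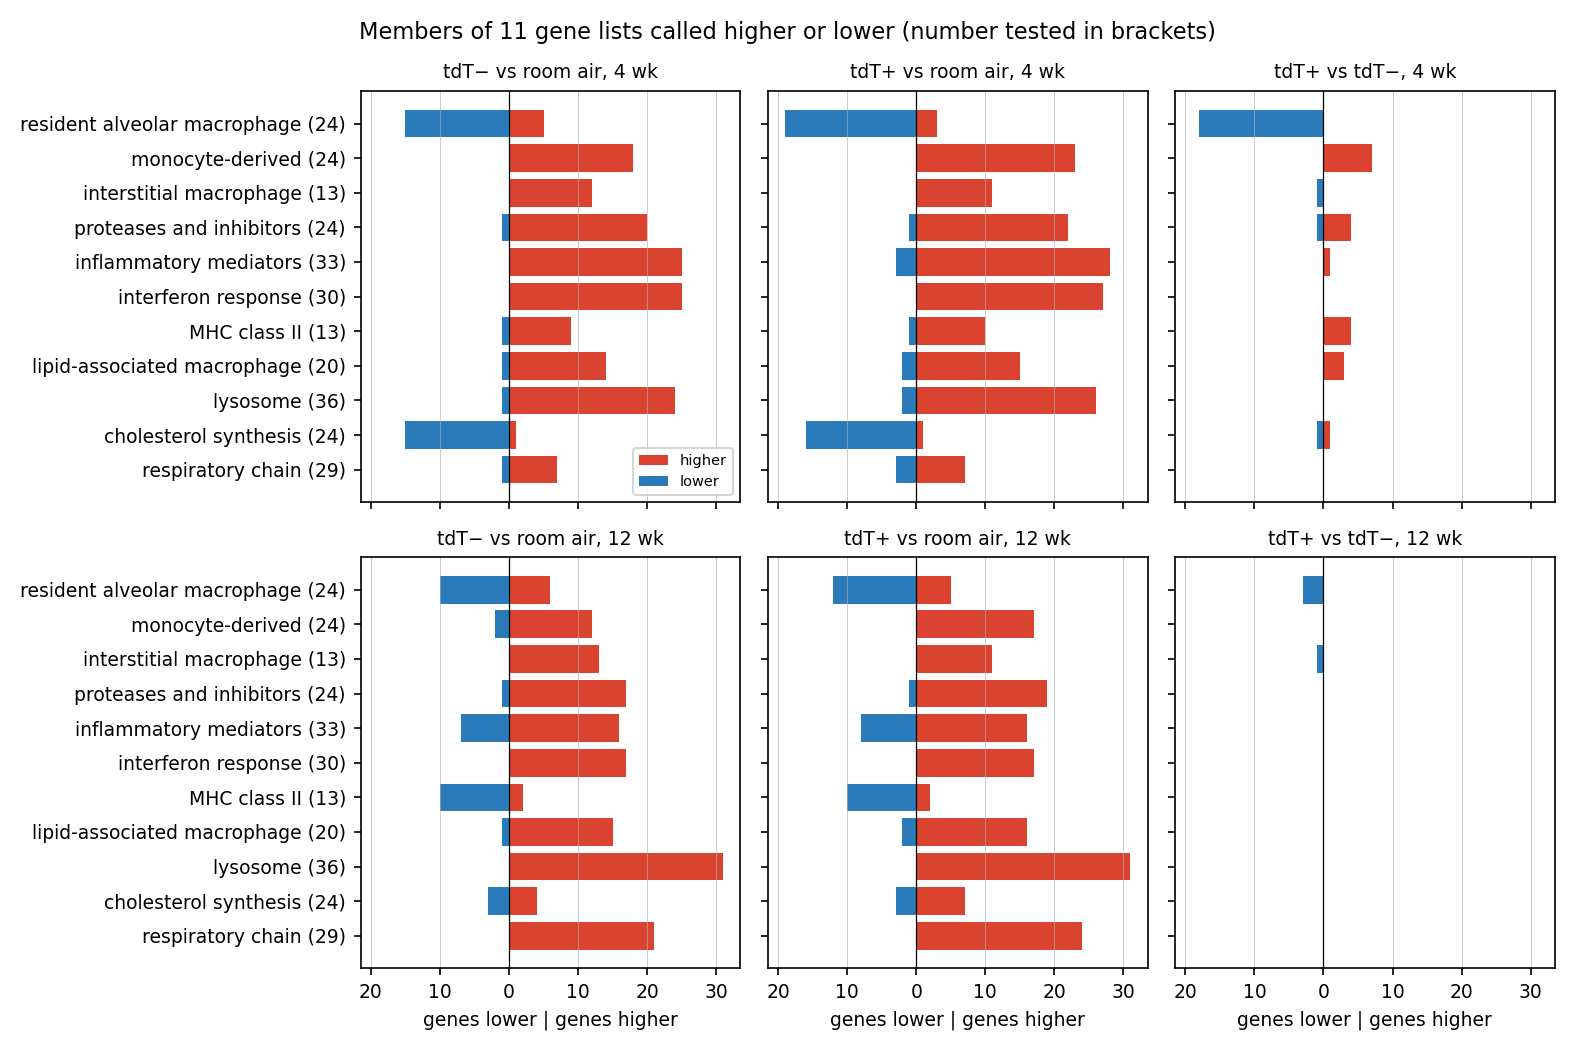
Number of genes called higher (red, to the right) or lower (blue, to the left) in 11 gene lists for each within-time comparison, with the number tested in brackets after each list name. The resident list had 15, 19 and 18 lower genes in the comparisons at 4 weeks, and 10, 12 and 3 at 12 weeks.

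Room air macrophages were compared between the times to see what the later experiment differed in without smoke. Genes of the rapid response to stimulation were higher at 12 weeks: the growth factor Ereg was at 137 ± 47.2 against 0.874 ± 0.292 CPM, and the nuclear receptors Nr4a3, Nr4a2 and Nr4a1 (852 ± 131 against 15.5 ± 0.833 CPM for Nr4a1; SD, n = 4) followed. Of 20 dissociation stress genes 19 were higher (19 adjusted over the list alone), with Fos at 2.97 and Zfp36 at 3.17. Cytokine genes were higher in 19 of 33 (19 adjusted over the list alone), such as Cxcl2, at 1282 ± 317 against 47.9 ± 10.3 CPM, and Tnf (3.17). Of the MHC class II list 8 of 13 were higher (8 adjusted over the list alone), with Cd74 at 2326 ± 329 against 643 ± 105 CPM. Ribosomal protein genes were lower in 26 of 30 (26 adjusted over the list alone), Rpl37 by 1.05. Protease genes were higher in 13 of 24 and lower in 2, the same adjusted over the list alone, with Mmp19 at 2.19. Among genes that met the conditions for naming the largest falls were in the zinc finger gene Zfp128 (-1.95 ± 0.26) and in Mir142hg (-1.67 ± 0.21). Resident genes were higher in 5 of 24 and lower in 3 (the same adjusted over the list alone), while endothelial and mesenchymal genes were higher in 8 of 13, Cdh5 from 4.65 ± 0.975 to 13.3 ± 3.53 CPM.

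By the same edgeR test 3579 genes were higher and 3783 lower in room air at 12 than at 4 weeks, with an adjusted p of 1.3e-12 for Ereg and 2.0e-14 for Nr4a1 (Benjamini-Hochberg). The camera adjusted p was 1.9e-35 for stress, 4.1e-18 for cytokine, 0.00241 for MHC class II, 2.2e-07 for ribosomal and 9.9e-04 for protease genes. Of the 10 calls the stress list held with an estimated correlation (adjusted p = 0.00485), and the others did not (0.393 for cytokine and 0.950 for MHC class II, ribosomal and protease genes). Exposure time, age and the experiment cannot be told apart in this comparison.

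The difference of each smoke group from the unsplit room air cells of the same time is called the smoke effect here. Its change from 4 to 12 weeks was tested for each of the lineages. In tdTomato-negative cells it was lower at 12 weeks for MHC class II genes, 8 of 13 (10 adjusted over the list alone), with Cd74 at -3.34 ± 0.37 and H2-Ab1 at -3.54 ± 0.40 log2 units. Ccr2 (-2.24 ± 0.24), Ccl2 (-3.25 ± 0.43), Inhba (-4.46 ± 0.68) and Nr4a3 (-5.28 ± 0.67) also had lower effects at 12 weeks. For Nr4a3 and Ccl2 this lay mainly in room air. Nr4a3 rose there by 6.63 log2 units from 4 to 12 weeks, more than its effect fell. Ccl2 rose there from 0.828 to 6.50 CPM, while in the smoke cells it went from 100.1 to 83.6 CPM. Cytokine genes had a lower effect in 12 of 33, interferon genes in 7 of 30 and monocyte-derived genes in 3 of 24, or 20, 21 and 12 adjusted over the list alone. The median change of the cytokine list from 4 to 12 weeks was 1.91 log2 units in room air, along with the rise of the dissociation stress genes there, and 0.04 in these smoke cells (-0.20 in tdTomato-positive ones). The largest higher effect among genes that met the conditions for naming was in Olfml3, a secreted olfactomedin (2.10 ± 0.42). No resident gene was called, on all genes or adjusted over the list alone, and the effects on Siglecf, Mmp12 and Gpnmb did not pass either.

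In tdTomato-positive cells the deficit of the resident program against room air was smaller at 12 weeks. Whether these cells had lost the program or never had it cannot be told without tdTomato-positive room air cells. The effect was higher for 15 of 24 resident genes (17 adjusted over the list alone), with Ear1 at 2.38 ± 0.30, Krt19 at 2.29 ± 0.37 and Siglecf at 1.49 ± 0.34 log2 units. Car4, which was not lower than in room air at 4 weeks, also had a higher effect at 12 weeks (1.55 ± 0.32). The effect was lower for 15 of 24 monocyte-derived genes (18 adjusted over the list alone), with Ccr2 at -2.60 ± 0.26 and Cx3cr1 at -2.19 ± 0.37, and for Mmp12 (-2.10 ± 0.43). MHC class II genes had a lower effect in 10 of 13, cytokine and interferon genes in 18 of 33 and 18 of 30, and dendritic cell genes in 8 of 11, or 12, 19, 23 and 11 adjusted over the list alone. Cholesterol synthesis genes had a higher effect in 13 of 24 and fatty acid oxidation genes in 10 of 22 (16 and 17 adjusted over the list alone), such as Acat2 (1.15) and Ech1 (1.14). Without the shallow library these were 9 and 5.

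The difference between lineages was then compared between the times. The gap was smaller at 12 weeks for Cpne5 (ENSMUSG00000024008), 1.90 ± 0.22 log2 units, the 1 gene called, named because no other was. Of the resident list no gene passed over all genes and 14 of 24 had a smaller deficit adjusted over the list alone. In room air that list changed little from 4 to 12 weeks, median 0.11 log2 units over the full-depth libraries, and its change was 0.43 in tdTomato-negative and 1.39 in tdTomato-positive cells.

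The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 112 genes higher and 532 lower for the change of the tdTomato-negative effect, 981 and 1540 for that of the tdTomato-positive effect, and 1 and 0 for that of the lineage difference. For the last, 1661 genes had an unadjusted p under 0.05, DESeq2 called 14 higher, voom 16 higher and 2 lower, and pool as a block gave 198 and 136. Without 1 library the lineage count rose to as many as 59 higher (without tdTomato-positive replicate 1 of 12 weeks) and 23 (without tdTomato-positive replicate 3 of 4 weeks), and the tdTomato-negative count to 218 higher (without tdTomato-negative replicate 3 of 4 weeks). The lower tdTomato-negative count was 308 and 346 without room air replicate 1 or 3 of 4 weeks, 339 and 345 without room air replicate 1 or 4 of 12 weeks, and 352 without tdTomato-negative replicate 3 of 12 weeks. Without the shallow library the tdTomato-positive counts were 656 and 1948. By camera the resident list was called for the lineage difference (adjusted p = 3.4e-10, and 0.979 with an estimated correlation) and the tdTomato-positive effect (4.4e-12, and 0.580), and MHC class II genes for both effects (5.0e-11 and 1.8e-08, and 0.226 and 0.576 with an estimated correlation).

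Genes called in both of a pair of comparisons were counted. For tdTomato-negative cells 2793 genes were higher at 4 and at 12 weeks, where independent lists would share 786.2, and 2053 were lower at both, where they would share 620.5. For tdTomato-positive cells these were 3082 (1037) and 2728 (1092). Between lineages, 10 genes were higher and 49 lower in tdTomato-positive cells at both times (0.306 and 2.68), and with pool as a block 166 and 259 (19.5 and 38.2). The lineages of 1 time shared 3564 higher and 2996 lower genes at 4 weeks and 3717 and 3490 at 12 weeks, but both were set against the same room air libraries. Simulated counts with no effect gave 0 shared calls, a correlation of log2 fold changes across genes of 0.493 at 4 and 0.470 at 12 weeks and a covariance of 0.05002 and 0.0817. The observed correlation was 0.908 and 0.862 and the covariance 1.65 and 1.43, and with the room air libraries split so that each lineage had its own, the correlation was 0.857 to 0.867 and 0.820 to 0.848. The lineages of 1 time were also taken to share pools of smoke-exposed mice, which neither the simulation nor the split accounts for.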

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

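The comparisons, the genes fixed in advance, the alternatives, the random splits and the test of gene length and GC content were set before their results were seen. The other tests of explanations and the runs without the library of 12656 counts were chosen after.

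The smoke effect, the difference of a smoke group from unsplit room air cells, differed between the times for many genes. In tdTomato-negative cells 112 genes had a higher and 532 a lower effect at 12 than at 4 weeks (edgeR quasi-likelihood). Olfml3 was at 2.10, Cspg4 at 1.65, Clec2d at 1.403 and Slco2b1 at 1.27 log2 units, and Nr4a3 at -5.28, Inhba at -4.46, Cxcl3 at -4.39, H2-Eb1 at -3.94 and Ccr2 at -2.24. The calls of Cspg4 and Slco2b1 were lost without several single libraries, for instance room air replicate 1 of 4 weeks (edgeR adjusted p = 0.06245 and 0.0519). In tdTomato-positive cells 981 genes had a higher and 1540 a lower effect. The largest among genes that met the conditions for naming were Lars2 at 5.40, Acaa1b at 3.395, Chil4 at 2.75 and Rufy4 at 2.66, and Nr4a3 at -5.50, Inhba at -5.30, Cxcl3 at -5.06 and H2-Eb1 at -4.85. Lars2 fell to 0.41 without tdTomato-positive replicate 1 of 12 weeks (edgeR adjusted p = 0.423), and Acaa1b was not called by voom (2.98, adjusted p = 0.0553). Of the genes fixed in advance Siglecf was at 1.49, Car4 at 1.55, Ccr2 at -2.60 and Mmp12 at -2.10.

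The difference between the lineages changed in 1 gene and 0 the other way by edgeR, where 1661 genes had an unadjusted p under 0.05, DESeq2 called 14 higher and voom 16 higher and 2 lower. With pool as a block 334 genes were called, and at most 3 in any other of 35 splits of the pools.

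Single values stood apart in 3 of 76 groups of values tested, where chance alone picks about 1 in 20. They were Siglecf in room air replicate 1 of 4 weeks (393.4 CPM) and Nqo1 in tdTomato-positive replicate 2 of 4 weeks (3.47 CPM). The last, Nqo1 at 83.4 CPM in tdTomato-positive replicate 2 of 12 weeks, was 2 counts in the library of 12656.

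Random regroupings of the same libraries tested whether chance could give as many calls. Each was fitted on the libraries of the compared groups alone, so the real counts differ from those of the fit of all 24 libraries. Of 35 splits per comparison only 1, the real grouping, reached its count: 7941 genes against at most 0 in another split for tdTomato-negative and 9556 against 0 for tdTomato-positive cells at 4 weeks. At 12 weeks these were 8650 against 0 and 9104 against 0, and 9914 against 0 for room air. Between lineages the split counts were 789 against 1 at 4 weeks and 31 against 22 at 12 weeks. For the change of the effects 1 of 45 splits reached the real count, 1177 against 385 in tdTomato-negative and 2760 against 1204 in tdTomato-positive cells, and for the lineage difference 1 of 35 splits, 1 gene against 0. For the comparisons with room air and between room air groups only the real grouping of 35 reached its count, which argues against chance. The other splits mixed the compared groups, so their counts of 0 do not show how many of the calls are false. The splits for the change of both effects mixed libraries of both times within a group, which widens the spread even where the effect did not change. Their low counts therefore cannot tell whether chance gave the real counts. The lineages were taken to share pools, and only 8 of their splits divide each pool between the groups, too few for a share under 1 in 20. Over those 8, with pool as a block, the real grouping reached 3426 genes at 4 weeks against at most 0, and 1101 at 12 weeks against 1059, in the split that exchanged the library of 12656 counts with its partner. For the lineage difference between times whole pools were regrouped, and with pool as a block 334 genes stood against at most 3 in the other of 35 splits. Only the real grouping reached its count there too. The other splits mixed pools of both times, and the library of 12656 counts was in the fit. Their low counts therefore do not show how many of the 334 calls are false.

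MHC class II genes were higher with smoke at 4 weeks and lower at 12 weeks. A shift of the room air level alone is argued against by tdTomato-negative smoke libraries, whose own median fell by 0.9518 log2 units from 4 to 12 weeks while room air rose by 1.51. B cells in the room air libraries are argued against, since their summed markers rose by 0.143% of the rise of the class, from 11.9 to 16.0 CPM against 1342 to 4196 CPM. Dendritic cells in room air may add to the pattern, with a median of 0.0348 log2 units for their list in room air, a test that does not settle it. In smoke libraries that list fell from 4 to 12 weeks along with MHC class II, by a median of -1.95 in tdTomato-negative and -2.98 in tdTomato-positive cells. Dendritic markers were higher with smoke at 4 weeks, and although the SiglecF+ gate of the sort is meant to leave dendritic cells out, an admixture in the smoke libraries of that time stays open, also as a source of their fall in MHC class II.

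Immediate early and inflammatory genes were higher in room air at 12 than at 4 weeks. Different handling of the cells in the later experiment is a candidate explanation, since the dissociation list also had a median of 1.33 log2 units in tdTomato-negative smoke cells and 1.17 in tdTomato-positive ones, beside 2.03 in room air. Gene length or GC content is argued against: with its trend removed the median in room air was 2.10, against 2.03 before. Age of the mice and exposure time stay open, because each time was its own experiment.

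Fewer genes differed between the lineages at 12 than at 4 weeks. The library of 12656 counts does not account for all of it, because leaving out 1 tdTomato-positive library at 4 weeks still left at least 684 genes, against 77 at 12 weeks without that library. The size of the gap depended on the fit and on single libraries: without tdTomato-positive replicate 3 of 12 weeks 153 genes were higher and 322 lower. With pool as a block and without the library of 12656 counts 1619 were higher and 1365 lower at 4 weeks and 533 and 628 at 12 weeks. When 1 tdTomato-positive library of 4 weeks was left out of that fit too, so that 3 pools stood at each time, the total at 4 weeks was 1.87 to 2.13 times that at 12 weeks. With the same libraries left out of the fit without the block, which also held room air, the total at 4 weeks was 12.5 to 16.7 times that at 12 weeks. Much of the size of the gap thus depended on the fit. The block and the room air libraries were not varied apart, so the part of each is not known. A larger spread between pools as the whole cause is argued against by the size of the resident list difference, a median of -0.18 log2 units at 12 weeks and -1.32 at 4 weeks. That monocyte-lineage cells take on the resident program over time is a hypothesis that was not tested. The list rose from 4 to 12 weeks by a median of 1.39 in tdTomato-positive and 0.43 in tdTomato-negative cells, and a test would need cells marked at a known time and followed in the same experiment. Different animals and different cell ages at the times were not separated from this.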

How the results depend on the processing

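Runs without the library of 12656 counts in camera, the block fit and with RLE factors were chosen after the data were seen, and the other alternatives before. Among 678 results for named genes, none that was called in the main fit or in an alternative turned its direction. Changes of sign in results called in neither were not counted. Whether a result was called stayed the same in 604 with DESeq2, while 66 calls were lost and 2 gained. In runs that left out 1 library it stayed the same in 5217, with 310 calls lost and 25 gained. The counts of genes moved more, and the cause was not tested unless stated.

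DESeq2 called fewer genes higher than edgeR against room air: 2503 and 2842 at 4 weeks in tdTomato-negative and tdTomato-positive cells (4107 and 4691 by edgeR), and 1844 and 2034 at 12 weeks (4231 and 4887). For tdTomato-positive against tdTomato-negative cells it called 129 higher at 4 weeks (356), and 4 higher and 43 lower at 12 weeks (19 and 79). In room air at 12 against 4 weeks it called 1847 higher (3579). For the change between times it called 25 higher for the tdTomato-negative effect (112), 299 higher and 937 lower for the tdTomato-positive effect (981 and 1540) and 14 higher for the lineage difference (1). Genes higher in both of a pair were then 1431 for tdTomato-negative cells at 4 and 12 weeks (2793), 1499 for tdTomato-positive cells (3082), 1 for the lineage difference (10), 2182 for both lineages at 4 weeks (3564) and 1580 at 12 weeks (3717).

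With RLE factors, genes higher at 12 weeks were 2675 in tdTomato-negative and 2810 in tdTomato-positive cells, 11 between lineages, 73 for the change of the tdTomato-negative effect and 4 for that of the lineage difference. Without the library of 12656 counts all 20 counts with RLE factors were within 1.5 times the edgeR ones, so that library accounts for the gap. The stricter filter tested fewer genes and called 2600 higher in tdTomato-negative cells and 2986 higher and 2879 lower in tdTomato-positive cells at 4 weeks. At 12 weeks it called 2574 and 2583, 2973 and 2891, and 9 higher between lineages, with 2382 and 2237 for room air and 71 higher for the change of the tdTomato-negative effect. Without a filter the lineage change between times had 4 higher and 2 lower.

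An absolute log2 fold change of at least 1 left 2149 higher and 1545 lower in tdTomato-negative cells and 2403 and 2708 in tdTomato-positive cells at 4 weeks. At 12 weeks it left 1658 and 2330 in tdTomato-negative cells and 1783 higher in tdTomato-positive cells. Between lineages it left 89 and 434 at 4 weeks and 11 higher at 12 weeks, in room air 1453 and 1842, and for the changes of the tdTomato-negative and tdTomato-positive effects 58 and 457 higher. With voom, genes higher between lineages at 4 weeks were 941, genes lower in room air at 12 weeks 5905, and the change counts 398 and 827 (tdTomato-negative), 1573 higher (tdTomato-positive) and 16 and 2 (lineage difference). A separate fit per time gave 549 higher between lineages at 4 weeks, and 5 higher and 37 lower at 12 weeks.

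With pool as a replicate block, which removes differences between pools, the lineage counts were 1249 higher and 1321 lower at 4 weeks and 315 and 583 at 12 weeks. For the changes of the effects against room air, the block also tied room air libraries to smoke libraries of the same number, which come from other mice. It gave 395 and 964 for the tdTomato-negative effect and 1732 higher for the tdTomato-positive effect, counts that are not a correction for shared pools. For the lineage difference pool as a block gave 198 and 136 for its change between times, and 166 and 259 genes shared by both times. With the block and without the library of 12656 counts the lineage counts were 1619 and 1365 at 4 weeks and 533 and 628 at 12 weeks. The change then had 250 and 226, and 282 and 285 genes were shared. Camera in that setting called 19 lists at 12 weeks and 13 for the lineage change. Against split room air libraries, the lineages shared 2310, 2265 and 2327 higher and 1841, 1886 and 1948 lower genes at 4 weeks (3564 and 2996 unsplit). At 12 weeks these were 2298, 2154 and 2198 higher and 2083, 1995 and 2124 lower (3717 and 3490), with fewer controls in each test.

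Leaving out 1 library of the compared groups also moved the lineage counts. At 4 weeks they ran from 176 to 499 higher and 467 to 816 lower, and at 12 weeks from 1 to 153 higher and 18 to 322 lower. For the change of the tdTomato-negative effect they ran from 76 to 218 higher and 308 to 577 lower. For the lineage difference between times they ran from 1 to 59 higher and 0 to 3 lower: 11 and 2 without tdTomato-negative replicate 4 and 23 and 2 without tdTomato-positive replicate 3 of 4 weeks. Without tdTomato-negative replicate 1 or 3 of 12 weeks there were 2 and 7 higher, and without tdTomato-positive replicate 1 or 4 of 12 weeks 59 and 4. Camera called 14 lists for that difference without the library of 12656 counts, against 4 with it.

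Gene list calls rested on the correlation assumed between genes. With an estimated correlation, calls fell from 19, 17 and 15 lists at 4 weeks to 0, from 19, 16 and 11 at 12 weeks to 0, from 10 to 1 in room air, and from 17, 16 and 4 for the changes between times to 0. Fry called 5, 11 and 0 lists at 4 weeks, 4, 4 and 0 at 12 weeks, 2 in room air, and 0, 4 and 0 for the changes. Fry turned the direction of 19 lists, none called by it. In tdTomato-positive cells at 12 weeks these were MHC class I (adjusted p = 0.769 by fry), interferon (0.943), NRF2 (0.669), respiratory chain (0.674), iron (0.943) and growth factors (0.807). Between lineages at 12 weeks they were proteases (fry adjusted p = 0.324), lipid-associated (0.669), lysosome (0.508), glycolysis (0.354), neutrophil (0.251), dissociation (0.4399) and ribosomal genes (0.705). For the change of the tdTomato-positive effect they were lipid-associated (fry adjusted p = 0.751), lipid uptake (0.644), cholesterol (0.647), lysosome (0.8915) and respiratory chain genes (0.644), and for the lineage change ribosomal genes (0.537).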

Other observations

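The reporter locus was examined because Gt(ROSA)26Sor stood out at 12 weeks; its test over pools was written down before it was run. The gene lists, the fixed genes, their comparisons and the alternatives were set in advance, while the neighbours of the locus and the runs without the library of 12656 counts were chosen after the data were seen.

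Of 22 efferocytosis and scavenging genes 13 were higher and 4 lower in tdTomato-negative and 12 and 6 in tdTomato-positive cells at 4 weeks, and 12 and 1, and 9 and 3, at 12 weeks. The scavenger receptor Msr1 rose by 4.37 ± 0.17 log2 units and Mfge8, a bridge to dying cells, by 5.58 ± 0.35 in tdTomato-negative cells at 4 weeks. By camera the list was called in all 4 (adjusted p = 2.6e-07, 9.6e-05, 3.6e-08 and 6.4e-06; adjusted p = 0.361, 0.461, 0.443 and 0.548 with an estimated correlation). Iron genes were higher in 9, 8, 10 and 8 of 19 and lower in 3, 5, 2 and 2, with the metal transporter Slc11a1 at 4.16, 5.01, 3.06 and 3.35 (camera adjusted p = 0.00702, 0.0653, 8.3e-05 and 0.00247, and adjusted p = 0.581, 0.652 and 0.774 with an estimated correlation for the 3 called). Between lineages at 4 weeks efferocytosis genes were lower in 5 of 22 and iron genes lower in 3 and higher in 1 of 19, with the transferrin gene Trf at -1.385 ± 0.22.

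Growth factor genes were higher in 10, 11, 8 and 10 of 20 and lower in 3, 4, 3 and 5, in the same order, with Hbegf, a ligand of the epidermal growth factor receptor, at 4.24, 5.14, 3.75 and 3.95 (camera adjusted p = 3.1e-04, 7.0e-04, 0.00629 and 0.0141; adjusted p = 0.581, 0.561, 0.748 and 0.819 with an estimated correlation). Lipid uptake and efflux genes went both ways, 10 higher and 7 lower of 24 in tdTomato-negative cells at 4 weeks, 9 and 10 in tdTomato-positive cells, and 11 and 7 in each at 12 weeks. The fatty acid carrier Fabp5 rose by 1.53, 1.79, 1.78 and 2.46. For this list the median was -0.02 and the camera direction up in tdTomato-positive cells at 4 weeks (adjusted p = 0.110). Glycolysis genes were higher in 11, 14, 13 and 15 of 21.

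Targets of the smoke sensors went both ways. Of 28 NRF2 targets 12, 10, 10 and 10 were higher and 4, 8, 3 and 3 lower, with the cystine transporter Slc7a11 at 2.755, 3.17, 1.39 and 1.29. Camera gave an adjusted p of 0.0548, 0.138, 0.0117 and 0.0127 (0.767 and 0.819 with an estimated correlation for the last pair, and 0.0352 for the first without the library of 12656 counts). Of 9 AhR targets 4, 3, 4 and 2 were higher and 2, 1, 0 and 1 lower, with Ahr itself at 3.42, 4.01, 1.62 and 1.32 (camera adjusted p = 0.0263, 0.0270, 0.0947 and 0.263; for the first pair adjusted p = 0.564 and 0.471 with an estimated correlation, and 0.0656 and 0.0754 without the library of 12656 counts). The fixed gene Nqo1 was at 1.31 ± 0.34 in tdTomato-positive cells at 12 weeks, 3.69 ± 0.831 against 1.56 ± 0.498 CPM, and at 1.085 ± 0.32 in tdTomato-negative cells, calls DESeq2 did not make (adjusted p = 0.121 and 0.334). In tdTomato-negative cells at 4 weeks Nqo1 was at 0.82 ± 0.32 (edgeR adjusted p = 0.0481), a call lost without any of the room air replicates or tdTomato-negative replicate 1, 2 or 3 (adjusted p from 0.0569 to 0.232). Cyp1b1, at most 0.765 CPM as a group mean, was at 2.98 ± 1.13 in tdTomato-negative cells at 12 weeks (edgeR adjusted p = 0.0392), lost without room air replicate 1, 2 or 3 or tdTomato-negative replicate 2, 3 or 4 (adjusted p from 0.0589 to 0.101) and with DESeq2 (adjusted p = 0.190). Il1b was at 33.8 ± 18.1 against 10.52 ± 2.14 CPM in tdTomato-positive cells at 4 weeks (1.68 ± 0.44), with 60.6 CPM in replicate 4 and 21.5 to 28.5 CPM in the others. Spp1 rose by 3.55, 4.27, 4.50 and 4.33.

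MHC class I genes were higher in 5, 7, 5 and 6 of 13 and lower in 1, 1, 0 and 0, with Tap1, a peptide transporter, at 1.11 in the first of these (camera adjusted p = 0.261, 0.0562, 0.1502 and 0.0248, the last 0.819 with an estimated correlation, and the second 0.00456 without the library of 12656 counts). Circadian clock genes were higher in 6, 5, 7 and 6 of 14 and lower in 3, 3, 4 and 4, with Nr1d2 at 1.73, 1.66, 1.72 and 1.67, and in room air at 12 weeks 8 were higher and 3 lower, Dbp by -2.42. Whether the hour of collection differed between groups was not tested. Of the sort genes Itgax was at 2457 ± 368 against 1686 ± 133 CPM in tdTomato-positive cells at 4 weeks and Ptprc, which encodes CD45, at -0.93 ± 0.16. Xist, the 1 sex-linked gene tested, was at -0.42, -0.58, -0.65 and -1.15, and did not pass between lineages or in room air, while with pool as a block in edgeR it was lower in tdTomato-positive cells at 12 weeks (-0.53, adjusted p = 0.0499).

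Other markers were few. T and NK genes were higher in 6, 5, 2 and 2 of 16, led by Il7r and Cd4, and B cell genes in 1, 1, 0 and 0 of 8. Mast, basophil and erythroid genes were called in 0 of 5 in each smoke comparison and lower in 2 in room air at 12 weeks, Alas2 (-1.65 ± 0.45) and Hba-a1 (-2.36 ± 0.87), named after their values were seen. Of 2 eosinophil genes Ear6 was higher in all 4, by 4.08, 2.73, 3.98 and 3.89. Respiratory chain genes were higher in 7 of 29 and lower in 1 in tdTomato-negative cells at 4 weeks and in 7 and 3 in tdTomato-positive cells.

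Gt(ROSA)26Sor, on chromosome 6 from 113067428 to 113077333, was higher in tdTomato-positive than in tdTomato-negative cells in 7 of 7 pools with full-depth libraries. It stood at 14.0 ± 0.6003 against 8.94 ± 0.672 CPM at 4 weeks (SD, n = 4) and at 18.4 ± 2.65 (n = 3) against 7.09 ± 0.180 CPM (n = 4) at 12 weeks, with 11.2 ± 0.628 and 10.9 ± 1.04 CPM in room air. Its neighbours Thumpd3 (-0.12 and 0.02 log2 units) and Setd5 (-0.07 and -0.27) did not pass at 4 or 12 weeks. Setd5 was lower at 12 weeks with pool as a block and without the library of 12656 counts (-0.31 ± 0.08, edgeR adjusted p = 0.0184). Transcription through a recombined reporter allele at this locus is a possible explanation for the 7 of 7 pools. Of these the 3 pools of 12 weeks led to the choice of the gene, and the reporter's own sequence was not measured.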
